A study of Caenorhabditis remanei with 28 samples.

How the data were processed

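Poly-A RNA from pooled L1 larvae of Caenorhabditis remanei was profiled by sequencing in 28 libraries of 4 populations: the ancestor (n = 6, replicates 3 to 8), a control-selected population (n = 8), a heat-selected population (n = 8) and an oxidative-selected population (n = 6). Per the labels' protocols, worms were kept at 20 °C, embryos were isolated by bleaching and held in buffer without food for 20 h, the hatched larvae passed a filter of 20 µm, and about 100000 larvae per replicate were frozen. Also per the labels' protocols, poly-A RNA was purified on beads, sheared to fragments of 200 to 600 nt and copied to cDNA with barcoded adaptors.

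The authors deposited 1 table of raw counts per library, with the number of reads assigned to each of 25337 gene identifiers and 5 summary lines for reads not assigned to a gene. Per the submitters' processing notes, reads were aligned with GSNAP and counted with HTSeq; the genome build, the annotation and the strand setting are not given in the sources used here. Without the strand setting, reads of overlapping genes on opposite strands cannot be told apart, and genes with a near-identical copy could have lost reads that aligned to more than 1 place. The 5 summary lines were kept out of library sizes and tests. Reads outside annotated genes made up between 10.6% and 39.1% of all reads in a library, and unaligned reads between 15.7% and 37.5%. A population whose alleles differ from the reference would lose reads at the alignment step, and reads outside genes leave fewer counts for the genes, so both shares were compared between populations and tried as covariates.

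The identifiers were looked up in a RefSeq gene table of the species (assembly PX506). None of its names, locus tags or accessions matched: 0 of 25337 identifiers were paired with a gene name. The 44 gene lists fixed before the data were examined (stress response, metabolism, development and tissue markers) therefore had no measured member, and the planned tests of gene lists were not run. No coordinates are given for the same reason.

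Library totals after leaving out the summary lines ranged from 1406684 to 15755610 counts with a median of 4875498. A level of 3 counts corresponded to between 0.190 and 2.13 CPM (gene counts scaled to a common library size), so that genes near 1 CPM rest on a few reads in the shallower libraries. No difference in depth between populations passed an exact permutation test (lowest adjusted p = 0.0844, oxidative against ancestor). All 86 pairs of libraries within a population were compared by a chi-square test of their counts; the chi-square per degree of freedom was between 2.09 and 96.1, and no pair held identical values, so each library was counted as 1 sample.

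Differential expression was tested in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with a minimum count of 10, which left 11952 genes, and library sizes were scaled by TMM. A quasi-likelihood model with 1 coefficient per population was fitted to all 28 libraries, and 6 pairs of populations and the hypothesis of no difference among the 4 populations were tested with Benjamini-Hochberg adjustment at 0.05. Standard errors were computed from the log2 fold change and its F statistic. Levels in the text are CPM of the TMM-scaled libraries, as mean ± SD over libraries. Principal components were taken from log2 CPM with a prior count of 2. Shares of reads were compared with two-sided exact permutation tests over all splits of the libraries, adjusted over 24 tests (4 measures in 6 comparisons). The comparisons, tests, filters and alternatives were fixed before the data were examined.

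The genes named were chosen by a rule fixed at the same time. For each comparison it took genes with a name first. As no gene carried a name, it took the 2 genes with the largest rise and the 2 with the largest fall among those with an adjusted p under 0.05, an average of at least 1 log2 CPM, and no overlap between the libraries of the populations compared. For heat against ancestor and oxidative against ancestor the rule allowed only genes with a name. The same choice by identifier was extended to these comparisons outside the rule, and FL81_06792, FL81_16774, FL81_20150 and FL81_04032 were chosen only in this way. FL81_24102, FL81_24805, FL81_02553, FL81_23115 and FL81_06793 also fall outside the rule and were named after their values were seen. The value of FL81_06792 in heat against control was also given after it was seen.

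The test was tried on simulated counts, drawn for the real genes from the real means, dispersions and library sizes, with 200 genes changed by known folds in each comparison. For heat against control it found 28.4% of the genes changed 1.5-fold, 65.7% of those changed 2-fold and 93.9% of those changed 4-fold, with 8 false calls among 11705 genes. For oxidative against control the shares were 16.4%, 59.7% and 90.9%, with 6 false calls among 11722 genes.

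Overlap between comparisons that share the control libraries was set against 20 simulations of unchanged populations and against all 70 assignments of the control libraries to the comparisons, 4 to each. Because these called fewer genes on average than the real comparisons, lists of the same length as the real ones, made of the genes with the smallest p, were compared as well, a test added after seeing the data. Scores on the 3 leading components were set against 5 measures of the libraries as deviations from population means, with 100000 permutations within populations. Alternatives fixed in advance were RLE size factors, no filter, a stricter filter (1 CPM in every library of a population), the replicate number as a block, DESeq2 1.42.0, limma-voom (limma 3.58.1) with sample weights, a fit of only the populations compared, a minimum log2 fold change of 1, and leaving out each library. Alternatives added after seeing the data were replicates 1 to 6 only, replicates 7 and 8 only, leaving out heat replicates 1 and 2, leaving out heat replicates 3 to 6, the share of reads outside genes or of unaligned reads as a covariate, and 3 surrogate variables (sva 3.50.0). To see whether the counts of genes could arise from any grouping, each comparison was repeated on 100 splits of its libraries, the real one included.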

Results

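Gene expression was compared among 4 populations of Caenorhabditis remanei, a nematode with separate males and females. The ancestor was the laboratory strain PX443, and 3 populations derived from it had been selected for heat resistance, selected for resistance to oxidative stress, or kept as a selected control. The comparisons addressed which genes differed in expression after selection for each kind of stress resistance when the larvae had not been exposed to that stress. Embryos were synchronised by bleaching and incubated for 20 h without food, and poly-A RNA was taken from pools of about 100000 larvae at L1, the first larval stage. The series design places all libraries at 20 °C, although the protocol names 30 °C as another incubation temperature and the sample names of the heat and oxidative libraries carry no temperature. There were 6 ancestor, 8 control, 8 heat and 6 oxidative libraries. Each selected regime was represented by 1 population, so that a difference between populations can come from selection or from drift. The labels do not say whether libraries of a population came from separate cultures, so p-values measure the spread between these libraries, which may be partly technical.

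The number of reads assigned to genes ranged from 1406684 to 15755610 per library, with a median of 4875498. The ancestor libraries held between 4534564 and 15755610 gene counts, the control libraries between 1809122 and 15447168, the heat libraries between 1406684 and 9357212, and the oxidative libraries between 3103341 and 5754254. Of 25337 gene identifiers, 2764 had no count in any library and 11952 were abundant enough to be tested. The files do not pair these identifiers with gene names, so genes are given by identifier, and their functions and positions are not stated. Reads that aligned outside annotated genes made up 28.5% ± 6.73 (SD, n = 8) of all reads in the heat libraries and 18.4% ± 3.70 (n = 8) in the control libraries, a difference larger than the spread between libraries (two-sided exact permutation test, p = 0.000777, adjusted p = 0.00932 over 24 such tests). Unaligned reads made up 35.1% ± 1.91 (n = 6) in the oxidative libraries and 24.9% ± 6.08 (n = 8) in the control libraries (exact permutation test, p = 0.002997, adjusted p = 0.0144). The ancestor libraries held 16.2% ± 4.61 of reads outside genes and 23.8% ± 6.28 unaligned (n = 6).

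**Figure D1:**
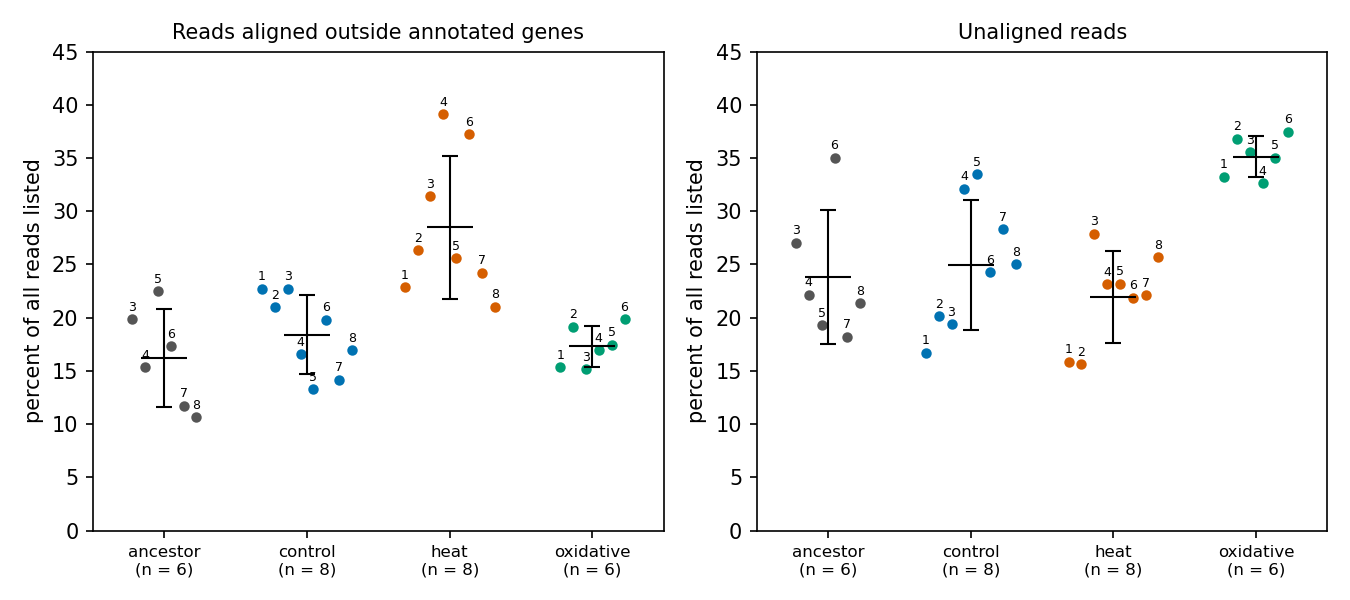
Percent of all reads that aligned outside annotated genes (left) and that did not align (right) in each library, grouped by population; points are libraries labelled with their replicate number, and black lines are the mean ± SD. Heat replicates 3, 4 and 6 had the highest shares outside genes (31.4%, 39.1% and 37.3%), and the oxidative libraries lay between 32.6% and 37.5% unaligned.

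The 6 oxidative libraries resembled each other most. Each had another oxidative library as its closest in log2 CPM (gene counts scaled to a common library size), against 5 of 8 control, 5 of 8 heat and 3 of 6 ancestor libraries with a closest library of their own population. Ancestor and control replicates 7 and 8 and heat replicate 7 each had a closest library numbered 7 or 8 in another population. The oxidative population had no libraries with these numbers. The median standard deviation of a gene among libraries was 0.28 log2 units in the oxidative population, 0.41 in the control, 0.43 in the ancestor and 0.48 in the heat population. The oxidative libraries also spanned the narrowest range of depth, and the effect of depth on these values was not tested. The leading principal component held 33.2% of the variance, of which population accounted for 4.57%. Components 2 and 3 held 14.2% and 8.48%, with 55.4% and 56.5% of each accounted for by population. On component 3, heat replicates 3 to 6 scored between -29.4 and -26.3, below every other library, of which heat replicate 2 was the nearest at -18.8. Replicates 7 and 8 of the ancestor, control and heat populations also lay near each other, between -41.2 and -10.8 on component 2 and at 5.60 or above on component 3.

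**Figure D2:**
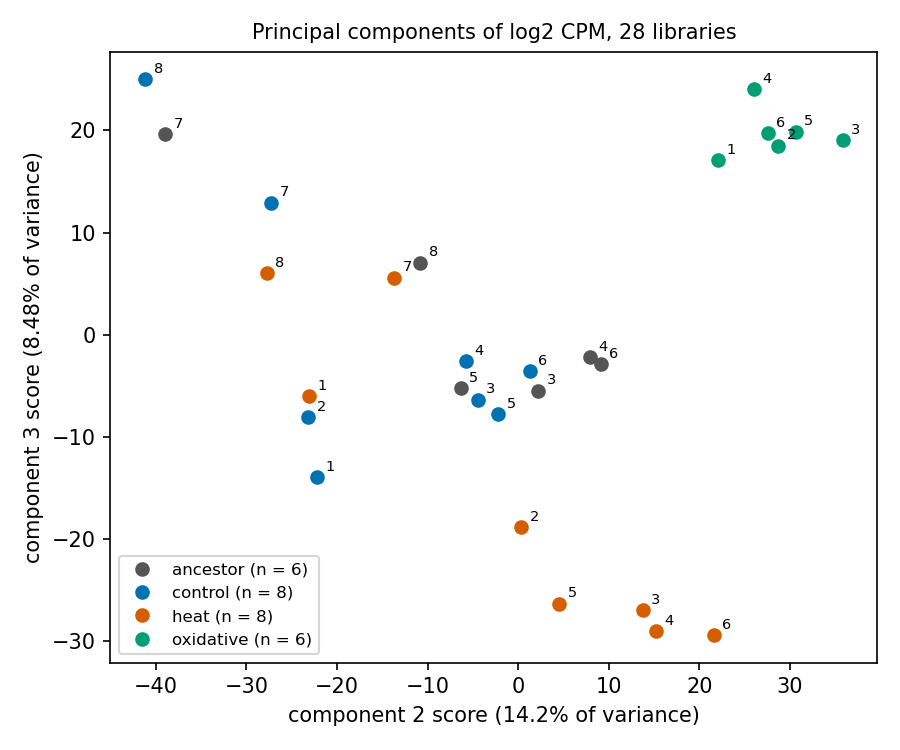
Scores of the 28 libraries on principal components 2 and 3 of log2 CPM (axes give the percent of variance), coloured by population and labelled with the replicate number. The oxidative libraries lie together at the upper right, with component 3 scores from 17.1 to 24.0, and heat replicates 3 to 6 lie together at the bottom.

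Larvae of the oxidative population differed from control larvae in 1675 genes, of which 817 were expressed at a higher level and 858 at a lower level, out of 11952 tested (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05, n = 6 and 8). The difference was at least 2-fold for 205 of the genes that rose and 368 of those that fell. As a group, the 817 genes that rose made up 9.27% ± 0.850 of gene counts in the oxidative libraries and 4.97% ± 1.03 in the control libraries, and the 858 genes that fell made up 8.63% ± 0.642 and 14.1% ± 1.76 (groups picked by the test on these same libraries). FL81_21398 rose from 0.703 ± 0.548 CPM in the control to 13.4 ± 1.84 CPM (log2 fold change 4.57, SE 0.47, edgeR adjusted p = 1.48e-07), and FL81_05979 rose from 3.02 ± 1.52 to 28.4 ± 4.80 CPM (3.31, SE 0.26, edgeR adjusted p = 5.37e-10). FL81_15447 fell from 6.53 ± 7.19 to 0.263 ± 0.163 CPM (-4.56, SE 0.83, edgeR adjusted p = 0.000429), and FL81_12861 fell from 9.49 ± 5.54 to 0.650 ± 0.435 CPM (-3.76, SE 0.56, edgeR adjusted p = 3.23e-05).

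The ancestor and heat levels of FL81_21398 (0.771 ± 0.622 and 0.495 ± 0.481 CPM) and of FL81_05979 (2.83 ± 1.09 and 2.60 ± 1.19 CPM) lay near the control level. The control mean of FL81_15447 was carried by replicates 7 and 8 (12.4 and 21.8 CPM, against 3.00 ± 1.95 in replicates 1 to 6), numbers that the oxidative population did not have. With replicates 1 to 6 alone, chosen after seeing the data, its fold change was -3.25 (edgeR adjusted p = 8.07e-05), that of FL81_21398 was 3.91 (edgeR adjusted p = 5.06e-08), and 1343 genes differed. The low levels of 3 of these genes also rested on few reads: each oxidative library held 0 to 2 counts of FL81_15447 and 0 to 6 of FL81_12861, and each control library held 0 to 5 counts of FL81_21398. Genes that differed were found at every level of abundance, from 110 higher and 175 lower among the 2988 least abundant genes to 302 higher and 265 lower among the 2988 most abundant. The count rose to 3566 with limma-voom and sample weights, to 3136 with the share of unaligned reads as a covariate and to 3735 with surrogate variables, the last 2 chosen after seeing the data.

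The oxidative population was also the one with the most genes that stood apart from all other populations. In that population 180 genes were higher and 235 lower than in each of the ancestor, control and heat populations (edgeR adjusted p under 0.05 in all 3 comparisons). In the heat population 15 genes were higher and 1, FL81_02867, was lower than in each of the others. In the control population 2 genes, FL81_20368 and FL81_24805, were lower than in each of the others. Without heat replicates 3 to 6, left out after seeing the data, the oxidative counts were 160 and 153, FL81_02867 was the 1 gene that met this criterion in the heat population, and neither FL81_20368 nor FL81_24805 met it in the control. The 15 genes became 6 to 9 without ancestor replicate 3, 4, 6 or 7 or heat replicate 3, 4, 5 or 6, and 26 to 29 without heat replicate 1, 7 or 8. The oxidative counts were between 118 and 143 higher and between 137 and 154 lower without ancestor replicate 8 or oxidative replicate 1, 4, 5 or 6, and 239 and 363 without heat replicate 1.

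**Figure D3:**
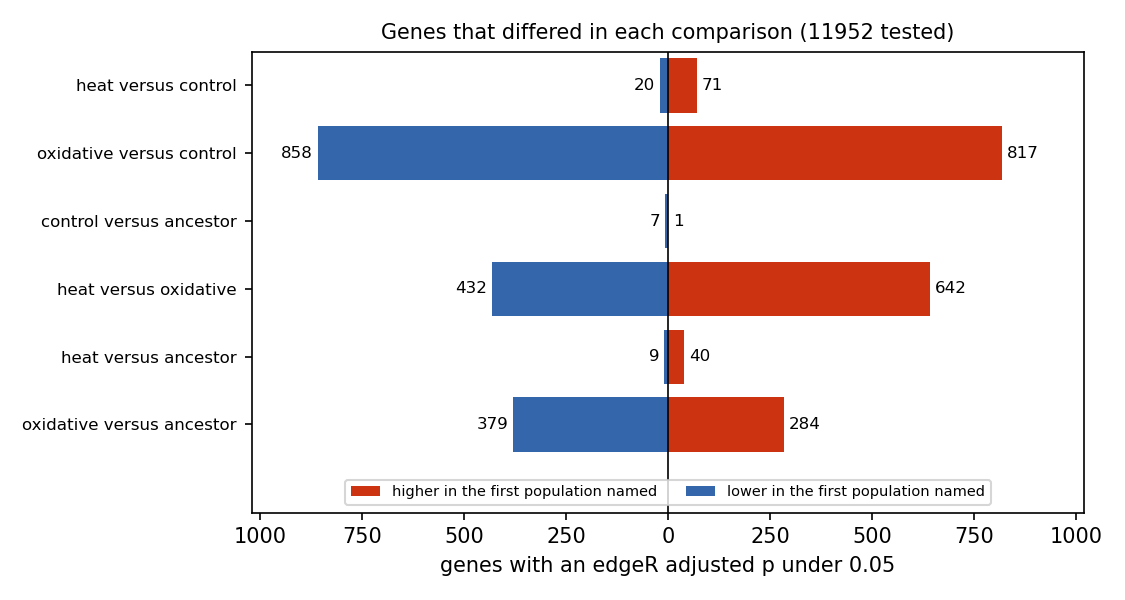
Number of genes with an edgeR adjusted p under 0.05 in each comparison, with genes higher in the population named first drawn to the right and genes lower in it to the left of 0. The bars of oxidative versus control (817 and 858) and heat versus oxidative (642 and 432) are the longest, and control versus ancestor has 1 and 7 genes.

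Heat larvae differed from control larvae in 91 genes, 71 higher and 20 lower (edgeR, adjusted p under 0.05, n = 8 and 8). FL81_02867 fell from 23.3 ± 7.31 CPM in the control to 1.16 ± 0.894 CPM in the heat population (log2 fold change -4.04, SE 0.34, edgeR adjusted p = 6.00e-09). All 8 heat libraries held between 0 and 2.57 CPM of it, below every library of the ancestor (13.4 ± 4.74, n = 6) and of the oxidative population (11.3 ± 4.10, n = 6). FL81_25082 fell from 60.6 ± 12.8 to 29.9 ± 8.97 CPM (-1.04, SE 0.24, edgeR adjusted p = 0.0314) and stood at 32.4 ± 8.25 CPM in the oxidative population, also below the control (-0.90, SE 0.26, edgeR adjusted p = 0.0198). FL81_16160 rose from 0.896 ± 0.389 to 2.93 ± 0.702 CPM (1.63, SE 0.36, edgeR adjusted p = 0.0217) and FL81_13436 from 1.45 ± 0.390 to 3.43 ± 1.32 CPM (1.22, SE 0.30, edgeR adjusted p = 0.0401). In heat against ancestor neither of these genes passed the threshold (1.06 and 0.52, edgeR adjusted p = 0.377 and 0.997). Their ancestor levels were 1.36 ± 0.961 and 2.36 ± 0.794 CPM. The low levels rested on 0 to 15 counts of FL81_02867 per heat library and on 1 to 14 counts of FL81_16160 and 3 to 15 of FL81_13436 per control library.

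The genes that were higher in heat larvae were not raised evenly across the 8 heat libraries. In 40 of the 71, the 4 highest heat libraries were replicates 3, 4, 5 and 6, which is 1 of 70 possible sets of 4. Over all 11952 genes that set was the highest in 527. FL81_06792, which was higher in heat than in control larvae (3.31, SE 0.62, edgeR adjusted p = 0.00575), stood at 135 to 174 CPM in heat replicates 3 to 6, at 3.19 to 6.38 CPM in the remaining heat libraries and at 4.88 to 14.2 CPM in the control libraries. Among the 20 genes that were lower in heat larvae, none had its 4 highest or 4 lowest heat values in replicates 3 to 6. With the 70 sets equally likely 0.286 of these genes would be expected per set, so this absence says little.

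With heat replicates 3 to 6 left out, an alternative chosen after seeing the data, 1 gene differed between heat and control larvae. That gene was FL81_02867 (-4.22, edgeR adjusted p = 1.14e-05), and leaving out any other set of 4 heat libraries gave between 2 and 412 genes with a median of 41. Leaving out 1 library gave 43 genes without heat replicate 3, between 48 and 50 without heat replicate 4, 5 or 6, 52 and 58 without control replicate 4 or 5, 139 without heat replicate 8 and 169 without heat replicate 1. The adjusted p of FL81_16160, FL81_25082 and FL81_13436 stayed under 0.05 in 23, 22 and 16 of the 28 fits that left out 1 library. Their directions held in all of them. Every lost call came from leaving out a heat or control library, as the ancestor and oxidative libraries are not part of this comparison. The call of FL81_13436 was lost without any 1 control library except replicate 2, and without heat replicate 1, 3, 4, 5 or 6. With replicates 7 and 8 alone, 2 libraries per population, FL81_02867 was again lower in heat larvae but past no threshold (-2.92, edgeR adjusted p = 0.231). With the share of reads outside genes as a covariate, 6 genes differed. The count also depended on the model, with 23 genes in a fit of only these populations, 171 with DESeq2 and 473 with limma-voom and sample weights. It was 242 with replicates 1 to 6 alone, 168 without heat replicates 1 and 2 and 787 with surrogate variables as covariates, the last 3 chosen after seeing the data.

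**Figure D4:**
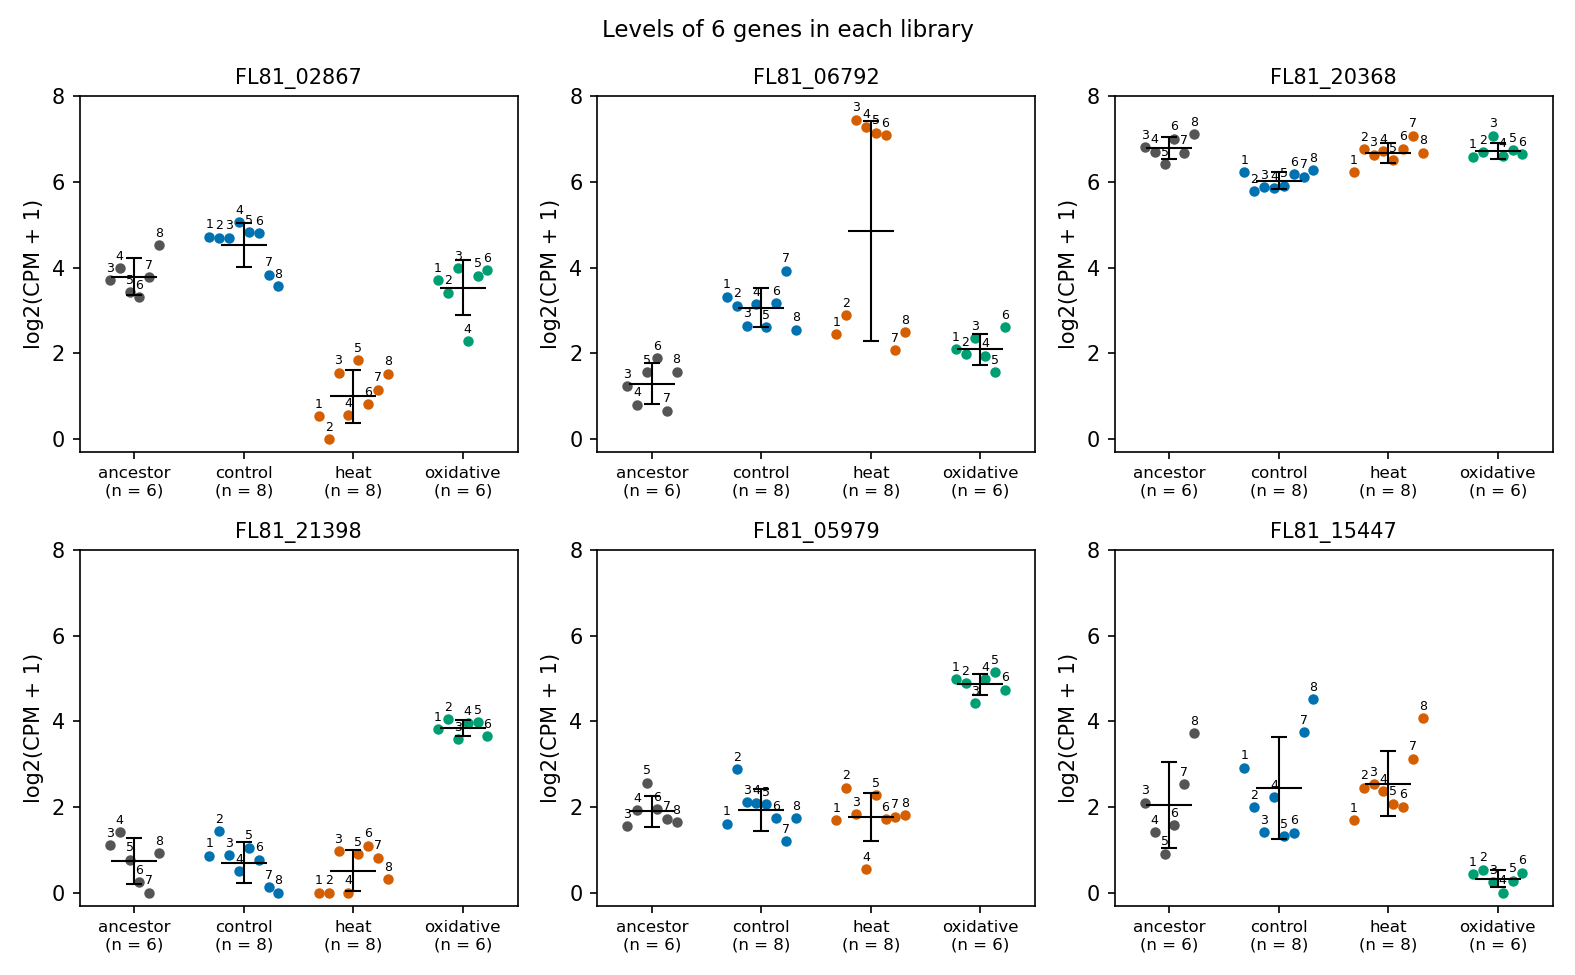
Level of 6 genes in each library as log2(CPM + 1), grouped by population; points are libraries labelled with their replicate number, and black lines are the mean ± SD of the plotted values. FL81_02867 is low in all 8 heat libraries, FL81_06792 is high in heat replicates 3 to 6, FL81_20368 is lowest in the control, and FL81_21398, FL81_05979 and FL81_15447 differ in the oxidative libraries.

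Both stress-selected populations were compared with the same control libraries, to ask whether the same genes differed in both. Of the 91 genes that differed in heat larvae, 47 also differed in oxidative larvae, 32 higher in both and 13 lower in both. FL81_16160 was among those higher in both, at 5.57 ± 1.06 CPM in the oxidative population (2.55, SE 0.36, edgeR adjusted p = 1.59e-05). FL81_02553 and FL81_23115, named here after their values were seen, were higher in heat larvae (0.83 and 1.90) and lower in oxidative larvae (-0.94 and -0.90). Lists of these sizes drawn independently would share 4.85 genes higher and 1.44 lower. Simulated unchanged populations tested against the same controls had 0.05 genes past the threshold in each comparison on average, too few to share any. When the 91 and 1675 genes with the smallest p were taken from each of the 20 simulations, a test chosen after seeing the data, 44.9 genes moved the same way in both lists on average (range 35 to 56). The observed 45 lay within that range. No gene was changed in these simulations, so the spread of the shared control libraries could fill both lists, whereas the real lists held genes past the threshold. In the same simulated lists 0.2 genes moved in opposite directions on average (range 0 to 1), against 2 observed. With the 8 control libraries split between the comparisons, 16.1 genes differed in heat and 963.2 in oxidative larvae on average over 70 assignments, of which 4.44 were shared (range 1 to 24). Lists of 91 and 1675 genes from the same assignments shared 30.7 that moved the same way (range 18 to 44) and 5.7 that moved in opposite directions (range 1 to 18). The observed 45 lay above the former range, but each of these comparisons held 4 control libraries in place of 8. The lists of equal length therefore do not settle how far the overlap comes from the shared controls. Across genes, which are not independent replicates, the log2 fold changes had a correlation of 0.38 and a covariance of 0.07. The correlation was 0.46 and the covariance 0.03 on average in the simulated unchanged populations, and 0.17 (range -0.18 to 0.33) and 0.03 (range -0.05 to 0.06) with the control libraries split. The observed covariance (0.0705) lay above the range of the simulations (0.0313 to 0.0355) and exceeded their average by 0.0366. The number shared was 14 in fits of only the populations compared, 72 with DESeq2, and 212 with limma-voom and sample weights. It was 98 with replicates 1 to 6 alone, 69 without heat replicates 1 and 2, 2 with the share of reads outside genes as a covariate and 363 with surrogate variables. Without heat replicates 3 to 6 the 2 comparisons shared 1 gene. Leaving out 1 library gave from 19 (heat replicate 3) to 71 (heat replicate 1) genes that moved the same way, with 21 to 27 without heat replicate 4, 5 or 6 or control replicate 4 or 5.

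Heat and oxidative larvae differed directly in 1074 genes, of which 642 were higher and 432 lower in heat larvae (edgeR, adjusted p under 0.05, n = 8 and 6). FL81_17394 stood at 226 ± 138 CPM in heat and 9.84 ± 3.02 CPM in oxidative larvae (log2 fold change 4.51, SE 0.46, edgeR adjusted p = 9.60e-08), with 118 ± 48.3 CPM in the control. FL81_15447 stood at 5.70 ± 4.46 and 0.263 ± 0.163 CPM (4.38, SE 0.85, edgeR adjusted p = 0.00113), with a fold change of 3.59 in replicates 1 to 6 alone. FL81_21398 was lower in heat larvae (-4.55, SE 0.49, edgeR adjusted p = 1.94e-07), as was FL81_05979 (-3.44, SE 0.27, edgeR adjusted p = 3.48e-10). The 446 genes that differed at least 2-fold included 320 higher in heat larvae. The count was 3133 with limma-voom and sample weights, 2847 with the share of unaligned reads as a covariate, and 3464 with surrogate variables. It was 1813 without heat replicates 1 and 2, 1717 without heat replicate 1 and 661 without heat replicates 3 to 6. The fold change of FL81_17394 was 3.41 in the latter fit.

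Control larvae differed from the ancestor in 8 genes, 1 higher and 7 lower (edgeR, adjusted p under 0.05, n = 8 and 6). FL81_20368 fell from 111 ± 19.5 CPM in the ancestor to 64.8 ± 8.93 CPM in the control (log2 fold change -0.77, SE 0.13, edgeR adjusted p = 0.0102). Its level was 102 ± 17.2 CPM in heat and 106 ± 14.7 CPM in oxidative larvae, both above the control (0.66 and 0.70, edgeR adjusted p = 0.00514 and 0.000455). The gene that rose was FL81_24102, from 3.99 ± 1.29 to 9.66 ± 3.33 CPM (1.22, SE 0.24, edgeR adjusted p = 0.0329), and FL81_24805 fell from 28.4 ± 14.2 to 12.6 ± 3.06 CPM (-1.18, SE 0.23, edgeR adjusted p = 0.0314); both were named after their values were seen. At an unadjusted p under 0.05 there were 470 genes, fewer than the 597.6 that chance alone would give. In simulated libraries of these depths the test found 62.7% of genes changed 2-fold and 13.4% of those changed 1.5-fold, so most differences of 1.5-fold would be missed. The count was 1 in a fit of only these populations, 5 with the stricter filter, 17 with DESeq2, and 71 with limma-voom and sample weights. In alternatives chosen after seeing the data it was 13 with the share of reads outside genes as a covariate, 52 with replicates 1 to 6 alone, 4 with replicates 7 and 8 alone and 193 with surrogate variables. It was between 3 and 5 without ancestor replicate 3, 4, 5 or 6 or control replicate 4 or 6, and 20 without ancestor replicate 7. FL81_20368 had an edgeR adjusted p of 0.0592 without ancestor replicate 6 and of 0.191 in a fit of only these populations.

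Set against the ancestor in place of the control, oxidative larvae differed in 663 genes, 284 higher and 379 lower (edgeR, adjusted p under 0.05, n = 6 and 6). FL81_20150 rose from 5.01 ± 2.06 to 88.3 ± 10.8 CPM (log2 fold change 4.12, SE 0.51, edgeR adjusted p = 6.48e-06), and FL81_21398 rose by 4.10 (SE 0.48, edgeR adjusted p = 2.20e-06). FL81_15447 fell by 3.89 (SE 0.87, edgeR adjusted p = 0.00654), and FL81_04032 fell from 12.1 ± 14.5 to 0.798 ± 0.450 CPM (-3.99, SE 1.03, edgeR adjusted p = 0.0194). The ancestor mean of FL81_04032 was carried by replicates 7 and 8 (30.6 ± 4.84 CPM, n = 2, against 2.91 ± 0.680 CPM, n = 4, in replicates 3 to 6), and its low level rested on 2 to 6 counts per oxidative library. With replicates 1 to 6 alone the fold changes were -1.89 for FL81_04032 (edgeR adjusted p = 0.0385) and -2.71 for FL81_15447 (edgeR adjusted p = 0.00292), and 520 genes differed. Of the 1675 genes that differed from the control, 569 also differed from the ancestor in the same direction and 1666 lay on the same side of it. Both comparisons use the same oxidative libraries, and in simulated unchanged populations lists of the same lengths shared 272.9 genes on average (range 252 to 294), with 1467.2 (range 1441 to 1490) on the same side. The call for FL81_04032 was lost without ancestor replicate 8 (edgeR adjusted p = 0.0753). The count was 2756 with limma-voom and sample weights, 2302 with the share of unaligned reads as a covariate and 2761 with surrogate variables. It fell to between 400 and 430 without ancestor replicate 8 or oxidative replicate 1, 4, 5 or 6.

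Heat larvae differed from the ancestor in 49 genes, 40 higher and 9 lower (edgeR, adjusted p under 0.05, n = 8 and 6). FL81_02867 fell by 3.27 (SE 0.35, edgeR adjusted p = 2.28e-06). FL81_06792 stood at 78.1 ± 79.3 CPM in heat larvae and 1.55 ± 0.807 CPM in the ancestor (log2 fold change 5.62, SE 0.82, edgeR adjusted p = 0.000600), and FL81_16774 at 53.7 ± 39.0 and 12.9 ± 1.73 CPM (2.05, SE 0.37, edgeR adjusted p = 0.00387). For FL81_16774 the heat libraries fell into separate ranges, 74.8 to 108 CPM in replicates 3 to 6 and 15.8 to 21.3 CPM in the others. Without heat replicates 3 to 6, 3 genes differed, and neither FL81_06792 (1.51, edgeR adjusted p = 0.288) nor FL81_16774 (0.50, edgeR adjusted p = 1.00) was among them. The adjusted p of FL81_06792 was 0.0532 with limma-voom and sample weights, and that of FL81_16774 was 0.0880 with edgeR in a fit of only these populations. The count was 9 in a fit of only these populations, 90 with DESeq2 and 138 with limma-voom and sample weights. In alternatives chosen after seeing the data it was 13 with the share of reads outside genes as a covariate, 164 with replicates 1 to 6 alone, 2 with replicates 7 and 8 alone, 88 without heat replicates 1 and 2 and 450 with surrogate variables. It was 27 to 29 without ancestor replicate 3, 4 or 6 or heat replicate 4 or 5, and 79 without heat replicate 7.

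Over all 4 populations, 1181 genes (9.88% of those tested) passed a joint test of any difference (edgeR quasi-likelihood test over the 3 population coefficients, adjusted p under 0.05, n = 28 libraries). The joint test was adjusted separately, and fewer genes passed it than the 1675 called in oxidative against control alone. The count was 3823 with limma-voom and sample weights, 2039 with the share of unaligned reads as a covariate and 4228 with surrogate variables.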

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

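The tests on a separate batch of the oxidative libraries and on heat replicates 3 to 6, the relations of the components, the splits that divided replicates 7 and 8 evenly, and the fits with a share of reads as covariate, were chosen only after the results they bear on were seen.

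In 68 sets of 6 or 8 libraries of a population, 10 held a library far from the others, where chance gives about 3.4. Ancestor replicate 8 had 15755610 gene counts, against at most 6887393 in the other ancestor libraries. In the same library FL81_15447 stood at 12.3 CPM, FL81_12861 at 8.14 CPM and FL81_17394 at 118.9 CPM, each the highest of the ancestor libraries. FL81_05979 stood at 4.94 CPM in ancestor replicate 5 and at 6.37 CPM in control replicate 2. FL81_15447 reached 15.9 CPM and FL81_04032 22.6 CPM in heat replicate 8. FL81_06792 stood at 14.2 CPM in control replicate 7, and FL81_20368 at 135 CPM in oxidative replicate 3. The share of reads outside genes in the heat libraries (28.5%) and of unaligned reads in the oxidative libraries (35.1%) stood above the control libraries, in reads that the comparisons of genes did not use.

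More genes differed from the control in oxidative larvae (1675) than in heat larvae (91). The tables argue against a smaller spread among the oxidative libraries with true differences of the same size, since the variance of true log2 differences, estimated from independent sets of libraries so that spread adds nothing on average, was 5.93 times as large in oxidative as in heat larvae (3.60 to 24.9 with any 1 library left out). They also argue against a linear trend with the share of unaligned reads as the whole cause, since 3136 genes differed with that share as a covariate. Other effects of that share stay open, because the oxidative libraries (32.6% to 37.5% unaligned) barely overlapped the control libraries (16.7% to 33.5%). A separate handling or sequencing batch of the oxidative libraries stays open, because 0 of the 6 had its closest library in another population, so that batch and population cannot be told apart. Selection for oxidative resistance and drift in this 1 population also stay open, as untested.

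The share of reads outside genes was higher in heat than in control libraries, and a trend with sequencing depth is argued against as the whole cause, because the difference was 8.67 percentage points (SE 2.13) with log2 depth in the model and 10.1 without it. Whether these reads account for the fold changes of the 91 genes stays open: with the share as a covariate the median ratio of the new to the old log2 fold change was 0.667 (interquartile range 0.473 to 0.931), all 91 kept their sign, and the calls mostly ended because the median size went from 1.27 to 0.94 while the median SE went from 0.268 to 0.350. A condition of heat replicates 3 to 6 alone is a candidate explanation for the genes that were higher, whose median ratio was 0.396 (interquartile range 0.202 to 0.834) without those libraries and 0.689 to 1.28 without any other 4 heat libraries. It is argued against as the whole cause for the 20 genes that were lower, with a median ratio of 0.873 (interquartile range 0.756 to 0.937), although the other sets of 4 all gave more (0.876 to 1.16). That condition may be technical or biological: the labels give no batch, replicates 3, 4 and 6 had the highest shares of reads outside genes, and an incubation at 30 °C, which the protocol names, was not tested because no library labelled with that temperature was analysed here.

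Each count of genes was set against 100 splits of the libraries compared, the real one included. Only the real split gave as many genes in oxidative against control (1675, highest other 360) and heat against oxidative (1074, highest other 60). The same held in oxidative against ancestor (663, highest other 142). Every other division drawn from these libraries thus gave far fewer genes there. The real split is always counted, so 1 of 100 is the lowest share that could be found, and it is not adjusted over the comparisons. The share of splits with as many genes was also under 0.05 for any difference among populations (2 splits, 1181 genes, highest other 1984). It was under 0.05 for heat against control too (3 splits, 91 genes, highest other 452). These shares do not exclude chance on their own, since other splits gave more genes and no adjustment was made over the comparisons. For control against ancestor the share was under 0.05 as well (3 splits; 8, highest other 1898), but whether these populations differ stays open. There, 470 genes had an unadjusted p under 0.05 where chance gives 597.6, and the variance of true log2 differences was estimated at -0.00562. The alternatives called between 1 gene (a fit of only these populations) and 193 (surrogate variables), with 17 by DESeq2, 52 in replicates 1 to 6 and 71 by limma-voom. For heat against ancestor, 7 splits gave as many (49, highest other 3395), so chance cannot be excluded over all splits. The splits treat the libraries as exchangeable, although replicates 7 and 8 stood apart from the others. Among splits that divided these numbers evenly, as the real one did, none of 41 others reached 49 genes in heat against ancestor (highest 29) or 91 in heat against control (highest 30), and 1 of 43 others reached 8 in control against ancestor (1311). Splits with several times the real count point to a structure of the samples: those with 452, 1898 and 3395 genes placed 38.7%, 52.3% and 53.0% of the variance of the leading principal component between their groups, against medians of 2.50%, 4.51% and 4.25%. Other splits reached the real count with less of that component between their groups, with 99 genes at 1.04% in heat against control and 64, 67, 115 and 123 genes at 11.9%, 3.29%, 0.165% and 7.39% in heat against ancestor. The splits with 99, 64, 67 and 115 genes, and that with 452, had all 4 libraries numbered 7 or 8 in 1 group, and that with 123 had 3 of the 4. Such a division was not enough to reach the real count: with all 4 in 1 group 2 of 4 splits did so in heat against control and 3 of 10 in heat against ancestor, and with 3 in 1 group 0 of 54 and 3 of 48.

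Within populations, scores on the leading component went with the TMM factor (r = -0.985, rho = -0.972), the share of counts in the 100 most abundant genes (r = 0.939, rho = 0.930), log2 depth (r = 0.740, rho = 0.725) and the share of unaligned reads (r = 0.577, rho = 0.581). For the TMM factor and the share, r and rho each had a permutation p of 1e-05, the smallest that 100000 permutations can give. For depth the permutation p was 4e-05 for r and 2e-05 for rho, and for unaligned reads it was 0.00361 and 0.00283. Over 15 relations the adjusted p was at most 0.0002 for the former 3 and 0.0102 and 0.00849 for unaligned reads. Without the 2 libraries farthest from the median the values of r were -0.977, 0.903, 0.709 and 0.615. They were -0.990, 0.986, 0.663 and 0.649 among the 22 libraries numbered 1 to 6 and -0.999, 0.903, 0.958 and 0.634 among the 6 numbered 7 or 8. The TMM factor and the share are computed from the same counts as the component, so they describe the make-up of the libraries and not its source. Component 3, on which heat replicates 3 to 6 stood apart, went with the share of reads outside genes over all libraries (r = -0.676, rho = -0.687, permutation p = 0.00136 and 0.00061, adjusted p = 0.0051 and 0.00229, with r = -0.628 without the 2 farthest libraries). With that share, component 3 had r = -0.638 among libraries numbered 1 to 6 and the opposite sign, 0.602, among the 6 numbered 7 or 8. Its relation to log2 depth (r = 0.630, rho = 0.535, permutation p = 0.00408 and 0.0112, adjusted p = 0.0102 and 0.0281; 0.522 without the 2 farthest) turned direction within these sets (r = -0.221 and -0.915), and its relation to the share of the 100 most abundant genes passed for rho (adjusted permutation p = 0.0399) but not for r (0.0695). Component 2 went with the share of reads outside genes (r = 0.572, rho = 0.523, permutation p = 0.00917 and 0.0159, adjusted p = 0.0196 and 0.0341; 0.471 without the 2 farthest), a relation that did not hold within both sets (r = 0.335 and -0.164). Within both sets, though, component 2 went with the TMM factor (r = -0.888 and -0.955). It also went with the share of the 100 most abundant genes (r = 0.864 and 0.758) and log2 depth (r = 0.671 and 0.836). Over all 28 libraries these values of r were -0.134, -0.055 and -0.282.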

How the results depend on the processing

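Fits limited to some replicates, without 2 or 4 heat libraries, with a share of reads as covariate or with surrogate variables were chosen after seeing the data. Over 824 refits of the named results, 773 kept direction and side of the threshold, 51 kept direction only, and 0 turned direction. Lost calls were in heat against control (FL81_13436, FL81_25082, FL81_16160), FL81_06792 and FL81_16774 against the ancestor, FL81_20368 and FL81_04032, and, with replicates 7 and 8 only, FL81_02867. RLE size factors moved no count by over 1.5 times. Depth limits what the shallow libraries show. Where no reason is given, the cause was not tested. The planned tests of gene lists, with camera and its alternatives, were not run because no identifier could be matched to a list.

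With a log2 fold change of at least 1 required, 56 genes remained in heat against control, 573 in oxidative against control, 446 in heat against oxidative and 292 in oxidative against ancestor. The stricter filter gave 5 in control against ancestor. DESeq2 gave 171 in heat against control, 17 in control against ancestor, 90 in heat against ancestor and 72 shared by heat and oxidative against control. Limma-voom with sample weights gave 473 in heat against control, 3566 in oxidative against control, 71 in control against ancestor, 3133 in heat against oxidative, 138 in heat against ancestor, 2756 in oxidative against ancestor, 3823 for any difference and 212 shared. Fits of only the populations compared, with fewer samples, gave 23 in heat against control, 1 in control against ancestor, 9 in heat against ancestor and 14 shared.

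Libraries with the same replicate number were not treated as pairs, because not every pair had correlated deviations above 0.1. Of 36 such pairs 20 did (median 0.15, range -0.35 to 0.67; -0.0020 for other numbers), and 10 of 28 libraries correlated best with their own number. In heat against control 7 of 8 did (median 0.27, lowest -0.24, and -0.05 for other numbers). In control against ancestor and in heat against ancestor 4 of 6 did, with a median of 0.29 in each (-0.04 and 0.03 for other numbers). A partial pairing stays open in these comparisons. In the others between 1 of 4 and 2 of 6 did. With the replicate block the counts were 180 in heat against control, 17 in control against ancestor and 87 shared, and the other counts moved by less than 1.5 times.

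Replicates 1 to 6 alone gave 242 genes in heat against control, 52 in control against ancestor, 164 in heat against ancestor and 98 shared. Replicates 7 and 8 alone, with 2 libraries per population, gave 4 in control against ancestor, 2 in heat against ancestor and 0 in heat against control, where edgeR found 329 genes at an unadjusted p under 0.05 (633.7 expected by chance) and no other tool was run. Without heat replicates 1 and 2 the counts were 168 in heat against control, 1813 in heat against oxidative, 88 in heat against ancestor and 69 shared. Without heat replicates 3 to 6 they were 1, 661, 3 and 1. The share of reads outside genes as covariate gave 6 in heat against control, 13 in control against ancestor, 13 in heat against ancestor and 2 shared. The share of unaligned reads gave 3136 in oxidative against control, 2847 in heat against oxidative, 2302 in oxidative against ancestor and 2039 for any difference. Surrogate variables gave 787 in heat against control, 3735 in oxidative against control, 193 in control against ancestor, 3464 in heat against oxidative, 450 in heat against ancestor, 2761 in oxidative against ancestor, 4228 for any difference and 363 shared. Split controls gave 4.44 shared on average, with 4 control libraries in each comparison.

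Leaving out 1 library at a time gave 43 to 169 genes in heat against control, 1120 to 2073 in oxidative against control, 3 to 20 in control against ancestor, 744 to 1717 in heat against oxidative, 27 to 79 in heat against ancestor, 400 to 978 in oxidative against ancestor, 800 to 1674 for any difference and 19 to 71 shared. The libraries behind changes of over 1.5 times are named beside each result.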

Other observations

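The tests on replicates 7 and 8, the values of replicates 1 to 6 alone and the tests on simulated lists of the same length were chosen after the results were seen; the test on neighbouring identifiers was chosen before its result was seen.

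Some genes averaged a few CPM or more in one population and close to none in another. Among genes past the threshold, 5 averaged over 5 CPM in oxidative larvae and under 1 CPM in the control, FL81_21398 among them, and 2 did so between oxidative and heat larvae. In the opposite direction, 9 averaged over 5 CPM in the control and under 1 CPM in oxidative larvae, but 8 of the 9 stood at 5 CPM or less in control replicates 1 to 6, and the oxidative population had no replicates 7 and 8. The exception was FL81_12861, at 4.73 to 18.9 CPM in control replicates 1 to 6. Of 8 genes that averaged over 5 CPM in heat and under 1 CPM in oxidative larvae, 5 likewise stood at 5 CPM or less in heat replicates 1 to 6. In 1459 of the 1675 genes that differed between oxidative and control larvae, the control mean lay nearer to the ancestor, and in 216 the oxidative mean did. In heat against control the corresponding numbers were 64 and 27 of 91, and 84 of the 91 lay on the same side of the ancestor as of the control, where lists of 91 genes from simulated unchanged populations gave 85.1 on average (range 80 to 89). Of the 91 genes, 25 also differed from the ancestor in the same direction. Simulated lists of the same lengths shared 6.85 genes on average (range 4 to 13). These groups share libraries with the tests that picked them, so they describe these libraries.

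Genes with neighbouring identifier numbers were often past the threshold together. Neighbours are next to each other in the order of tested genes, so untested identifiers can lie between them. In heat against control there were 6 such pairs that moved the same way, where a random order of identifiers would give 0.448. In these pairs 1 gene appeared more than once. The hypothesis that neighbouring genes vary together among libraries regardless of population was tested on splits of the heat and control libraries, and 12 of the 100 splits, the real one included, gave at least as many pairs (highest other 9), which is consistent with that hypothesis. In heat against ancestor there were 7 pairs and 1 of the 100 splits reached that number (highest other 6). The pair FL81_06792 and FL81_06793 (log2 fold changes 3.31 and 3.97 in heat against control; the latter named after its value was seen) was 1 of the 6.

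The replicate numbers 7 and 8 offered a check on libraries not used to pick genes. Of the genes that differed between heat and control larvae in replicates 1 to 6, 234 were measured in replicates 7 and 8, and 158 of these (67.5%) had the same direction there, against 58.8% of all genes. Their median size was 1.01 log2 units in replicates 1 to 6, and their median change in that direction was 0.18 in replicates 7 and 8. For control against ancestor the same direction was found in 23 of 47 genes (48.9%, all genes 49.8%) and for heat against ancestor in 79 of 154 (51.3%, all genes 48.5%), with median sizes of 1.34 and 1.46 in replicates 1 to 6 and median changes in that direction of -0.03 and 0.04 in replicates 7 and 8. No threshold was set for these shares, and genes are not independent of each other.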
